A study of Penicillium oxalicum with 6 samples.

How the data were processed

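Poly(A)-selected RNA from mycelia of Penicillium oxalicum, a filamentous fungus that secretes plant-polysaccharide-degrading enzymes, was sequenced in 6 libraries. Per the labels' protocols, strains were grown on potato dextrose agar plates at 28 °C for 4 days, spores were pre-cultured in glucose medium for 24 h, and the mycelium was moved to the test medium for 24 h. The treatment label and the design text name 1% Avicel (microcrystalline cellulose) as the test carbon source, whereas the treatment protocol names raw starch; the groups were taken as Avicel cultures, and this disagreement between the labels was not resolved. The genotype label put 3 libraries in the wild-type group (WT) and 3 in the group deleted for PoxTMA7 (ΔPoxTMA7). Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

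The authors deposited 1 table per library with a gene identifier and its FPKM (fragments per kilobase of gene, scaled to the sequencing depth), per the file headers. Per the submitters' processing notes, bcl2fastq was used; the aligner, the counting tool, the genome build, the annotation and the strandedness of counting are not given in the sources used here. No table held a gene at 0, so a gene absent from a library's table was set to 0. Of the 9137 gene identifiers listed in any library, 8252 were listed in all 6.

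The identifiers could not be joined to gene names. None of the 9137 matched the 9964 genes of the reference table used (assembly ASM172317v3), which follows another numbering and whose symbols are locus tags only. The files do not pair identifiers with names, products or coordinates. PoxTMA7 itself, and the lists of cellulase, hemicellulase, amylase, ribosome, secretion, conidiation and other genes that had been fixed by product name or protein motif, were therefore not analysed here, and no genomic coordinates are given. By the rule fixed for this case, the text names the 2 identifiers with the largest increase and the 2 with the largest decrease in log2 value, among genes with an adjusted p under 0.05, a mean of at least 5 FPKM and no overlap between the 3 WT and the 3 ΔPoxTMA7 values.

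Depth was read from the steps between low FPKM values. The ratio between libraries of the value of 1 read was taken from genes under 0.15 FPKM, and 102 to 160 genes gave the same ratio, within 0.006%, for each library after the first. A search for the total that makes gene lengths whole numbers of base pairs gave whole lengths (within 0.02) for 98.9% of the 536 genes used. It placed the totals at 11665908, 16508834 and 13911073 reads for WT replicates 1, 2 and 3, and at 13269238, 20808413 and 16208035 for ΔPoxTMA7 replicates 1, 2 and 3. The reads then recovered per gene summed to 99.6% to 99.7% of these totals, a quantity that was not used in the search. A gene with few reads, or whose reads share a common factor, can be recovered too low. At the median implied length, 3 reads corresponded to 0.0389 to 0.0695 FPKM, which is the limit of detection by counting error alone. The implied lengths had a median of 3702 bp, and 0.509% were under 2000 bp, against a median of 1330 bp and 74.2% under 2000 bp for genes of the reference table. The length assigned to each gene cancels in comparisons between libraries but affects the level of a short gene relative to a long one.

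The fixed design foresaw a count model for counts and limma for normalized values; since the files hold FPKM, the latter was used. Genes with at least 1 FPKM in at least 3 libraries were tested (6743 genes) on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model of genotype over all 6 libraries, empirical Bayes with an abundance trend, two-sided, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05). Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. A change of at least 2-fold means at least 1 on that scale. Other statistics were computed in Python 3.11.15 with SciPy 1.17.1, NumPy 2.4.6 and pandas 2.3.3. Values are FPKM as mean ± SD over n = 3 libraries.

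The fit was tested on simulated data for this comparison: reads were drawn for the real genes at the real depths with a dispersion of 0.03, and 200 genes were changed. Of the 6708 genes tested there, the fit recovered 28.4% of the genes changed 1.5-fold, 85.1% of those changed 2-fold and 100.0% of those changed 4-fold, and 5.96% of its 151 calls were unchanged genes. That dispersion is above the spread of the real replicates and far fewer genes were changed than were called, so these rates do not describe the real comparison. A simulation added after the data were seen used dispersions of 0.00367 for WT and 0.0182 for ΔPoxTMA7, set to the real median SD between replicates, and changed 3238 genes, mostly 1.5-fold. Of the 6716 genes tested there, the fit recovered 95.6% of the genes changed 1.5-fold and 100% of those changed 2-fold and 4-fold, and 2.52% of its 3178 calls were unchanged genes. It gave all genes of a group 1 dispersion and did not set ΔPoxTMA7 replicate 1 apart, so its rates may be too favourable. Replicates were compared by a chi-square of recovered reads over genes; the value per degree of freedom was 12.8 to 21.5 between WT libraries and 64.9 to 113.6 between ΔPoxTMA7 libraries. A value of about 1 would mean counting error of reads alone, which separate libraries are expected to exceed; no pair within a group was close enough to be taken as 1 library sequenced again.

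Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low values, the replicate number as a block, and leaving out each library. Alternatives added after the data were seen were median-ratio scaling, quantile normalization, totals without the 100 most abundant genes, a filter at 5 FPKM, and limma-voom on the recovered reads. Both groups carry the replicate numbers 1 to 3, but nothing in the labels ties equal numbers together.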

Results

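The transcriptome of Penicillium oxalicum was profiled by RNA sequencing in wild-type mycelium and in a mutant deleted for PoxTMA7, each with 3 libraries, after 24 h on 1% Avicel. The comparison was designed to ask how PoxTMA7 bears on the production of cellulases and xylanases, the enzymes that break down cellulose and xylan. The totals that scale the FPKM values, as recovered from their steps, were 11665908 to 20808413 reads per library. Reads outside these totals, if any, cannot be seen from FPKM. Libraries listed 8639 to 8794 genes each. Genes are given by the identifiers in the files, which carry no names or products, so neither PoxTMA7 nor any cellulase or xylanase gene is named.

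The main axis of variation separated the WT from the ΔPoxTMA7 libraries. On log2(FPKM + 1) of the 6743 tested genes, the first principal component held 80.5% of the variance and separated the 3 WT libraries, at -23.8, -23.8 and -25.5, from the 3 ΔPoxTMA7 libraries, at 12.9, 28.0 and 32.1. WT libraries correlated with each other at 0.993 to 0.995 across genes. ΔPoxTMA7 replicates 2 and 3 correlated at 0.991. ΔPoxTMA7 replicate 1 correlated with these at 0.976 and 0.971 and with the WT libraries at 0.95 to 0.957, whereas replicates 2 and 3 correlated with the WT libraries at 0.918 to 0.930. Genes are not independent replicates, so these correlations describe the libraries only. The median SD between replicates, on the log2 scale, was 0.083 in WT and 0.15 in ΔPoxTMA7. A range of 2-fold or more between the 3 replicates was seen in 39 genes in WT and 260 genes in ΔPoxTMA7. ΔPoxTMA7 replicate 1 carried most of this count: replicates 2 and 3 lay 2-fold or more apart in 28 genes, as against 6 to 30 genes for pairs of WT libraries and 155 and 197 genes for replicate 1 against replicates 2 and 3. The median SD of the pair of replicates 2 and 3 was 0.11, and those of the WT pairs were 0.061 to 0.072.

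**Figure D1:**
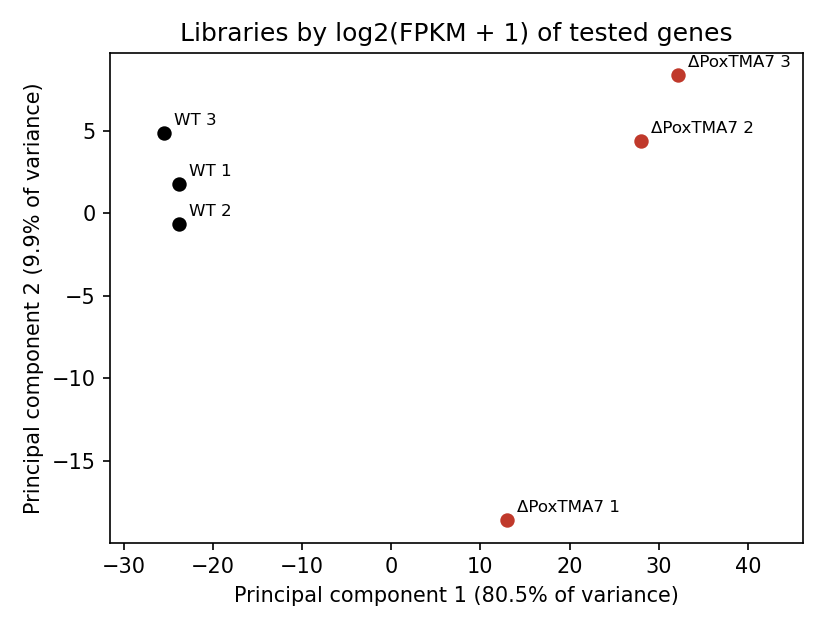
First and second principal components of log2(FPKM + 1) over the 6743 tested genes, 1 point per library (black, WT; red, ΔPoxTMA7), with 80.5% and 9.9% of the variance on the axes. The 3 WT libraries lie between -25.5 and -23.8 on the first component, and ΔPoxTMA7 replicate 1 lies at 12.9, between them and replicates 2 and 3. On the second component ΔPoxTMA7 replicate 1 lies at -18.6, apart from all other libraries, which lie between -0.66 and 8.35.

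Close to every other expressed gene differed in level between the mutant and WT, mostly by less than 2-fold. Of the 6743 genes tested, 2075 were higher and 1163 lower in ΔPoxTMA7 (3238 genes, 48.0%, limma, adjusted p under 0.05). The median size of these changes was 1.46-fold, and 85.8% of them were under 2-fold. At least 2-fold changes were found in 459 genes, 230 higher and 229 lower, and at least 4-fold changes in 31 genes that rose and 45 that fell. The 3 values of one genotype lay wholly outside those of the other in 4055 genes, 60.1% of those tested. Chance gives 10% for a single gene. All genes share the same 6 libraries and can shift together, so this share does not measure chance over genes.

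The balance of rises and falls depended on the scaling. The median change over all tested genes was 0.11 on the log2 scale (0.066 without ΔPoxTMA7 replicate 3, 0.13 without ΔPoxTMA7 replicate 2), and median-ratio scaling, which sets this shift to about 0, gave 1614 genes higher and 1633 lower. Among the changes of at least 2-fold, that scaling gave 179 higher and 303 lower. A pseudocount of 0.1 gave 437 higher and 292 lower at this size, and limma-voom on recovered reads gave 467 and 302. The number of changed genes was 3869 without ΔPoxTMA7 replicate 1, the library that stood apart from the other ΔPoxTMA7 libraries. Leaving out any other library lowered it, to between 2188 (without WT replicate 3) and 2703 (without ΔPoxTMA7 replicate 2).

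**Figure D2:**
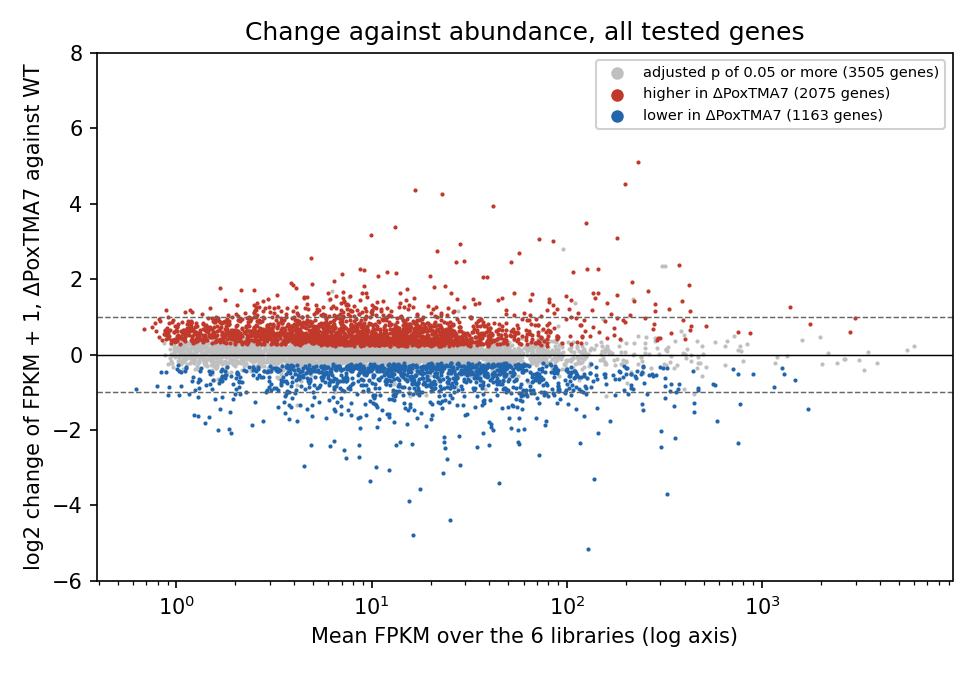
Log2 change of FPKM + 1 in ΔPoxTMA7 against WT (vertical axis) for each of the 6743 tested genes against its mean FPKM over the 6 libraries (horizontal log axis), with red for the 2075 genes that were higher, blue for the 1163 that were lower and grey for the others; dashed lines mark 2-fold. Lower genes make up a larger part of the calls among abundant genes than among weakly expressed ones.

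The 2 genes with the largest decrease kept at most a few percent of their mean WT level in the mutant. POX_1g01040 fell from 247.5 ± 131.7 FPKM in WT to 7.90 ± 9.51 in ΔPoxTMA7 (SD, n = 3), or to 3.19% of the WT mean (log2 change -5.16, SE 0.74, limma adjusted p = 0.00156). Its spread was wide in both groups, with 99.3 FPKM in WT replicate 2 against 292.3 and 351.1 in the other WT libraries, and with 18.9 FPKM in ΔPoxTMA7 replicate 1 against 1.94 and 2.89 in the others. POX_4g05484 fell from 32.2 ± 12.6 to 0.152 ± 0.027 FPKM (log2 change -4.79, SE 0.23, limma adjusted p = 2.84e-05), which is 0.47% of the WT mean. Between 1072 and 2657 reads were recovered for POX_4g05484 in each WT library, and 7, 9 and 10 in the ΔPoxTMA7 libraries. Because of the pseudocount its log2 change is understated: it was -6.94 with a pseudocount of 0.1 and -7.60 with limma-voom on recovered reads.

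The 2 genes with the largest increase had WT means near the level of the gene ranked 3000 (12.99 FPKM) and mutant means above that of the gene ranked 100 (316.9 FPKM). POX_6g07971 rose from 11.1 ± 1.19 to 448.0 ± 232.6 FPKM (SD, n = 3), a 40.4-fold increase of the mean (log2 change 5.10, SE 0.30, limma adjusted p = 6.82e-05). ΔPoxTMA7 replicate 2 reached 716.3 FPKM of POX_6g07971, against 324.2 and 303.4 in replicates 1 and 3. POX_4g05775 rose from 15.5 ± 0.552 to 379.1 ± 63.1 FPKM, a 24.5-fold increase of the mean (log2 change 4.51, SE 0.13, limma adjusted p = 4.24e-06). All 4 genes stayed past the threshold, in the same direction, without any single library and under each alternative run.

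**Figure D3:**
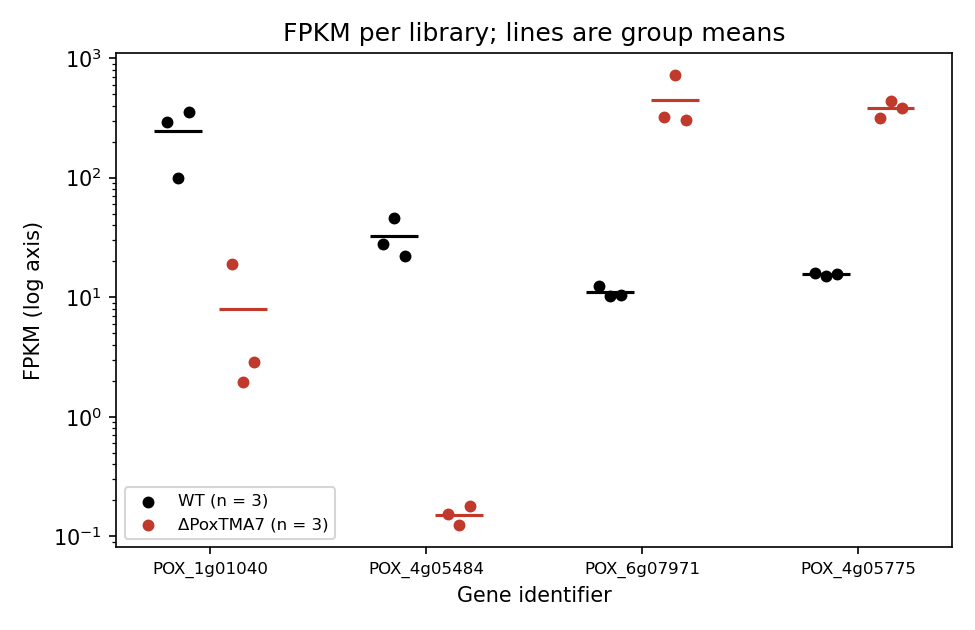
FPKM (log axis) of the 4 genes with the largest changes, 1 point per library (black, WT; red, ΔPoxTMA7; n = 3 each) and a line at each group mean. The groups do not overlap for any of the 4 genes, which was a condition for naming them. POX_1g01040 and POX_4g05484 are lower and POX_6g07971 and POX_4g05775 higher in ΔPoxTMA7.

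A check of the genotype on the deleted gene was not made, since PoxTMA7 could not be tied to an identifier. Of the 4585 genes with at least 5 FPKM in every WT library, none was missing from all 3 ΔPoxTMA7 libraries. The implied lengths exceed those of reference genes, so reads from flanking sequence could remain for a deleted gene. Its complete absence is therefore not required. In 1 of them, POX_4g05484, every mutant value was under 1% of the lowest WT value. Whether POX_4g05484 is the deleted gene, a neighbour of it or another gene could not be told. The mutant values were under 5% in 3 genes and under 10% in 5 genes. In the other direction, 6 genes had at least 5 FPKM in every ΔPoxTMA7 library and exceeded the highest WT value more than 10 times. Genes listed in all libraries of 1 genotype and in none of the other were few and weak. There were 11 such genes in WT, at up to 0.507 FPKM, and 15 in ΔPoxTMA7, at up to 0.211 FPKM.

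The direction of change differed between abundant and weakly expressed genes. Ranked by the mean of all 6 libraries, a grouping chosen after the data were seen, the 1000 most abundant tested genes included 188 that rose and 321 that fell, and the remaining genes 1887 that rose and 842 that fell (odds ratio 0.261, Fisher's exact test across genes, two-sided, p = 5.15e-42; genes are not independent replicates). Among the 100 most abundant genes, with means of at least 316.9 FPKM, 17 rose, 28 fell and 55 did not pass the test; 11 rose without WT replicate 1 or without WT replicate 3. In this class quantile normalization gave 21 rises and 22 falls, and median-ratio scaling 13 and 34, so its balance depended on the scaling. Genes ranked over 3000 held 1317 rises and 464 falls. The falls among them numbered 306 without WT replicate 1, 297 without WT replicate 3 and 729 with quantile normalization, and the filter at 5 FPKM left 685 rises and 292 falls. Outside the 1000 most abundant genes the falls numbered 547 without WT replicate 3 and 561 without WT replicate 1, in place of 842. The share of rises among calls was 36.9% in the 1000 most abundant genes and 69.1% in the rest. It was 25.3% and 54.7% with median-ratio scaling, and 45.3% and 55.8% with quantile normalization (Fisher's exact test, p = 1.63e-05). The 100 most abundant genes together held 39.6 ± 0.516% of the FPKM sum in WT and 39.0 ± 2.20% in ΔPoxTMA7 (SD, n = 3), a difference within the spread between replicates (exact permutation test, two-sided, p = 0.7). Genes at 1 FPKM or more numbered 6532 ± 25.9 in WT and 6741 ± 83.6 in ΔPoxTMA7, with no overlap between groups (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 libraries allow). That count uses the deposited scaling, under which genes ranked over 3000 had a median log2 change of 0.163. It was not repeated under another scaling, so it does not separate a shift in scaling from more genes being expressed.

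Changed genes were spread over the identifier groups. The number before the letter g in an identifier runs from 1 to 8 for nearly all genes; what it denotes is not given in the sources used here. Between 29.3% and 34.7% of the tested genes of each group were higher in ΔPoxTMA7, and between 15.4% and 19.1% were lower. A difference between the 8 groups in the proportions of higher, lower and other genes was not detected (permutation chi-square test across genes, p = 0.393). Group 6, which holds POX_6g07971, had 38 genes at least 2-fold higher and 22 at least 2-fold lower, and group 3 had 26 and 40; these contrasts were not tested.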

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

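Scaling, voom, the 5 FPKM filter and the totals without abundant genes were chosen after the data were seen; the other settings were fixed before the data were examined. The number of changed genes stayed within 1.5 times the reported 3238 under each alternative run. No reported call passed the threshold in the opposite direction, and calls that lost the threshold were not checked for direction. The number changed at least 2-fold, 459 as reported, rose to 729 with a pseudocount of 0.1 and to 769 with limma-voom on recovered reads; the genes higher at this size, 230 as reported, rose to 437 and 467. Both settings shrink low genes less, by construction. Leaving out 1 library gave 2188 to 3869 changed genes, the lowest without WT replicate 3 and the highest without ΔPoxTMA7 replicate 1, and 379 to 642 changed at least 2-fold. Of the 3238 calls, 67.2% were kept without WT replicate 3 and 97.3% without ΔPoxTMA7 replicate 1. Median-ratio scaling lowered the share of higher genes among calls from 64.1% to 49.7%, and quantile normalization to 54.1%, with 85.8% and 84.5% of the calls kept. With the replicate block, 2995 genes were changed, 1901 higher and 1094 lower, and 469 changed at least 2-fold; deviations of equally numbered libraries from their group means correlated at 0.022, 0.033 and 0.173, and WT replicate 2 correlated best with another number, so the numbers were not taken as pairs. The planned count-model fits and filters on counts were not run, since the files hold FPKM; results for PoxTMA7 and the gene lists could not be computed without gene names. Depth limits genes under about 0.0695 FPKM, the value of 3 reads in the shallowest library.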

Other observations

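Several tests were chosen after the result was seen. These were the tests of wild-type admixture, with its repeats on genes picked in separate libraries, and of runs of consecutive identifiers. The grouping by abundance, which the test of an even background also used, and the pair of identifiers in the last paragraph were chosen then too. So were the totals without the most abundant genes. The test of lower depth concerned a mutant library that stood apart in the data. The other tests are not claimed to have been set before the data were examined. POX_6g07971, the gene with the largest increase, was followed by 2 consecutive identifiers that also rose at least 2-fold, the smallest of the 3 changes being 1.94 on the log2 scale. It was the only run of 3 or more consecutive identifiers among the genes at least 2-fold higher, and chance orders gave as many genes in such runs often (permutation p = 0.106 over 1000 shuffled orders), so the run alone is not beyond chance. Pairs were: 41 of the 230 genes at least 2-fold higher and 34 of the 229 at least 2-fold lower sat in runs of at least 2 consecutive identifiers, against medians of 10 and 10 and highest values of 27 and 26 in shuffled orders (permutation p = 0.001 for both, the smallest that 1000 orders can give).

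Across all tested genes, log2 changes of adjacent identifiers correlated at 0.149, against up to 0.0451 in 1000 shuffled orders. Reads shared between neighbouring counting windows could give such a correlation at a distance of 1, and the implied gene lengths, with a median of 3702 bp against 1330 bp for genes of the reference table, make it a candidate explanation. A window would have to span several genes for it to act farther away, yet at distances of 3 to 5 identifiers the mean correlation was 0.0362, above the highest value of 0.0251 in shuffled orders. Distances 3 and 4, at 0.0552 and 0.0387, carried this mean, while the 0.0148 at distance 5 lay inside the central 95% of shuffled values (up to 0.0289). Sharing of reads therefore does not account for the whole pattern, and it stays open for the excess at a distance of 1. That identifiers follow the order of genes along the chromosomes is assumed here, and no biological explanation was tested.

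With the deposited scaling more genes rose than fell (2075 against 1163), but the size of this excess depended on the scaling. Median-ratio scaling, which sets the median change to about 0 by construction, gave 1614 and 1633, and 179 against 303 at 2-fold. Quantile normalization still gave more rises, 1687 against 1430, but 184 against 253 at 2-fold. A few abundant genes taking more of the WT reads could produce this through the scaling to totals. The median change stayed at 0.102 with the 100 most abundant genes left out of the totals. It lay between 0.0814 (without ΔPoxTMA7 replicate 3) and 0.111 when 1 library was also left out. In WT replicates 1, 2 and 3 these genes held 37.5%, 38.4% and 37.6% of the reads. In ΔPoxTMA7 they held 37.5%, 39.7% and 35.7%. With shares this similar, leaving them out could change little, so only these 100 genes were argued against as the source. Abundant genes ranked below them stayed in the totals, and their part in the shift was not tested. An even background of reads, such as genomic DNA, would raise silent genes by as many FPKM as others. The 1949 genes with a mean under 0.5 FPKM rose by a median of 0.0138 FPKM (0.00926 to 0.0176 when 1 library was left out), far below 0.279 FPKM, the rise taken as needed for such a background, while the tested genes ranked over 3000 rose by a median of 0.559 FPKM. Whether the shift is one of scaling or of the genotype stays open, and the design does not separate genotype from any other difference between the 2 sets of cultures.

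On the first principal component ΔPoxTMA7 replicate 1 lay between WT and the other mutant libraries. On the second component, with 9.87% of the variance, replicate 1 lay at -18.6 and all other libraries between -0.66 and 8.35. Replicate 1 was therefore not only intermediate but also stood apart from both groups. It was the nearest of the 3 to WT in 335 of the 459 genes changed at least 2-fold (73.0%, where an even spread gives 33.3%), and, with genes picked for a 2-fold change in replicate 2 or 3 against 1 WT library and measured in the libraries not used to pick them, its median change was 58.9% to 71.4% of that of the other replicate. Admixed WT RNA would need 1 share for all genes, but the median share was 0.481 in 285 genes that rose and 0.247 in 294 that fell, a difference of 0.234 (95% bootstrap interval 0.187 to 0.278; 0.180 to 0.251 with genes picked in separate libraries). Lower depth was also argued against, since with replicates 2 and 3 thinned to its depth its distance to them was still 1.51 times (1.45 to 1.60) their distance to each other. A culture at another stage of the response, or another batch, may account for it and was not tested.

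The number of changed genes, 3238, and of genes changed at least 2-fold, 459, was reached by 1 of the 10 splits of the 6 libraries into 3 and 3, the real one; the highest of the others was 0 for both. With 10 splits the share cannot be under 0.1, so this count cannot settle whether chance is excluded.

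Identifiers POX_12g10644 and POX_8g10629, picked out after their values were seen, agreed within 6.19% in all 6 libraries over a range from about 31 to 678 FPKM. WT replicate 1 held 456.8 and 430.1 FPKM, 12.9 and 12.3 times the mean of the other 2 WT libraries, and neither passed the limma test between genotypes (adjusted p = 0.0658 and 0.0615). Replicate 1 was also highest in both genotypes for most other tested identifiers with numbers above 8 before the letter g. The only exceptions were POX_16g10662 and POX_18g10669. POX_17g10663 held 10.4, 0.779 and 0.600 FPKM in WT replicates 1, 2 and 3, and 12.1, 7.33 and 5.15 in ΔPoxTMA7. POX_16g10662 was instead lowest in replicate 1 in both genotypes, at 30.7 FPKM in WT and 31.9 in ΔPoxTMA7. POX_18g10669 was lowest among the WT libraries in replicate 1, at 1.49 FPKM, but highest among the ΔPoxTMA7 libraries in replicate 1, at 1.95 FPKM. Whether equal replicate numbers are tied in these identifiers was not tested.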
